A study of Mus musculus with 9 samples.

How the data were processed

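The deposited files were 9 scanner outputs of two-colour Agilent arrays and 1 value table. Per the file headers, the intensity columns came from Agilent Feature Extraction 9.5.1.1, which gives for each spot the mean pixel intensity and the median local background in green (Cy3) and red (Cy5), not yet background-corrected. Per the labels, RNA of the ES cells was labelled with Cy3 and the common reference with Cy5 on every array, with no dye swap, so a dye bias of single probes does not cancel against the reference but is shared by all groups. The deposited log10 ratio of the scanner files is red over green, and its sign was turned so that all values rise with the sample.

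The deposited value table is on a log10 scale and holds 25030 of the 42034 non-control spots, with array medians from 2.173 to 2.19. At the probes named below that it holds, its changes between groups equalled those of the log10 ratio of the scanner files. This settles its scale and direction for changes between groups. How its rows were chosen is not stated. The value table was used only as an alternative.

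The background was corrected with normexp (offset 50) on all 43451 spots, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. M is the log2 ratio of Cy3 over Cy5. No normalization between arrays was applied. The 1417 control spots were left out, as were spots marked as non-uniform or as population outliers (4 to 16 per array), and 7 probes with several spots were averaged. No spot was saturated. Probes were tested if well above background in Cy3 on all 3 arrays of at least 1 group, which kept 24757 and left out 17249. Offset 50 draws the fold changes of dim probes toward 0.

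The 9 arrays were fitted together with lmFit, contrasts.fit and eBayes, so that the 3 groups share one estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all tested probes within each comparison, with a threshold of 0.05, and counts were also made with at least a 2-fold change. Every adjusted p given for a probe comes from this limma fit and is two-sided. An exact permutation test of 3 against 3 arrays cannot go below 0.1. The same steps were tested on simulated data, with 200 of 24757 probes changed in Tmx+ vs Tmx-. Of the 100 probes changed by 1 on the log2 scale all were recovered, 50 in each direction, and of the 50 raised and 50 lowered by 0.5, 48 and 49. There were 15 calls among unchanged probes. The simulated arrays all started from the mean of the control arrays, with noise in Cy3 only, drawn independently for each array. Effects of slide or position and a deviating array were not simulated, so the recovery is that of a favourable case.

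The lists of genes and the rule for naming genes were set before the data were examined. The rule took the 12 largest rises and 12 largest falls in Tmx+ vs Tmx-, and the 10 and 10 in each other comparison, among genes with a symbol that passed the test, had groups without overlap and were well above background on all 3 arrays of 1 group. Since no probe carries a gene name, the 23 gene lists, the check of Zscan4 and the reduction to 1 probe per gene could not be run, and the rule was applied to probes, of which the 2 with the largest rise and the 2 with the largest fall per comparison are given by ID. The probe sequences were not matched to a genome or to transcripts here.

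Sequence families were built from blastn 2.17.0 matches of probe against probe on the same strand, over at least 40 bases with at least 85% identity. Reference classes were tested with limma's fry and camera on the 6 arrays of Tmx+ and Tmx-, with a preset correlation of 0.01 and with an estimated one. The arrays lay on 3 slides. Slide 1 held the control arrays and Tmx- replicate 1, slide 2 the other Tmx- arrays and 2 Tmx+ arrays, and slide 3 the last Tmx+ array. Slide was tried as a fixed and as a random block and by comparing within slides 1 and 2. Other alternatives changed the background correction, the normalization, the use of the reference, the filter, the variance model, the replicate number as a block, the arrays included and the source of the values. In the fit with slide as a fixed block, Tmx+ vs Tmx- is estimated within slide 2 and Tmx- vs control within slide 1.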

Results

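Gene expression was measured on 9 two-colour microarrays in mouse embryonic stem (ES) cells of the hybrid line V6.5. The cells fell into 3 groups of 3 arrays each. The control group was clone #2, transfected with the neomycin-resistance control and cultured for 3 days. The other groups were clone #18, which carries a transgene for Zscan4 fused to ERT2, cultured for 2 days without tamoxifen or with 200 nM tamoxifen. Zscan4 encodes a zinc finger protein that is expressed in the 2-cell mouse embryo and, at any one time, in a small part of cultured ES cells. ERT2 is a mutated estrogen receptor domain that keeps a fused protein inactive until tamoxifen binds it. The labels do not say whether the replicates were separate cultures. If they were not, the counts of called probes and the adjusted p-values below do not measure variation between cultures.

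Each array carried the sample in Cy3 and a common reference in Cy5. Per the labels, the reference was a pool of RNA from 11 cultured mouse cell lines mixed 2:1 with RNA of another ES line. The level of a transcript is given as M, the log2 ratio of sample to reference. Mean Cy3 intensity lay between 1243 and 2151 per array, over a median local background of 43 to 47, and 58.0% to 63.3% of the 42006 distinct probes were well above background in Cy3. The 24757 probes well above background on all 3 arrays of at least 1 group were tested, and the number of arrays limits the precision. Across those probes, M correlated between arrays of one group with r from 0.992 to 0.995, except that Tmx- replicate 1 correlated with the other uninduced arrays at 0.982. Its residual SD around the group mean was 0.121, against 0.0504 to 0.0777 on the other 8 arrays.

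The files pair none of the probes with a gene: on all 9 arrays, 0 of the 42034 non-control spots carried a name other than the probe's own ID. None of the 42006 probe IDs occurred in the mouse gene table supplied with the data. The level of Zscan4, which would have checked the transgene and the labels, could therefore not be read, and neither could any pluripotency, embryonic or stress gene. Probes are reported below by ID and 60-base sequence, and in groups defined by their behaviour or by their level in control ES cells.

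The first comparison, induced against uninduced cells of the Zscan4-ERT2 clone, addresses what tamoxifen changed within the clone at the same culture time. No array held the control clone with tamoxifen. Effects of tamoxifen itself and of the activated fusion protein therefore cannot be told apart. Tamoxifen was followed by higher signal at 5204 probes and lower signal at 4260 (limma, adjusted p below 0.05), 38.2% of those tested, and most of the changes were small, with a median size of 0.27 on the log2 scale. At least 2-fold changes were fewer: 105 probes rose and 198 fell. These 2-fold counts differed with the processing, with 375 and 487 in Agilent's processed ratio, 337 and 398 in the deposited value table, and 197 and 258 with offset 10. At least 4-fold changes were more often falls, with 16 against 2 rises. On all 303 of the 2-fold probes the 3 induced arrays lay above or below the 3 uninduced arrays without overlap. Their selection on the same arrays makes this likely, so it adds no support. Over all tested probes the groups did not overlap at 47.8%, where chance gives 10%.

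The largest rises were at 2 probes whose order changed with the background correction. One was Z00015795-1 (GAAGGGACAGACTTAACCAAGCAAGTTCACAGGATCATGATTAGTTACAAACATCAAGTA), from M of -1.87 ± 0.13 (SD, n = 3) without tamoxifen to 0.21 ± 0.03 (SD, n = 3) with it. This log2 change of 2.07 (SE 0.08, limma adjusted p = 1.19e-07) started from a level close to the control clone's, -1.85 ± 0.17. Probe Z00003224-1 (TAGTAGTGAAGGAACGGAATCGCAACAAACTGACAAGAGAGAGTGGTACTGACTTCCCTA) rose by a log2 change of 2.03 (SE 0.05, limma adjusted p = 6.38e-09). Its uninduced level of -0.43 ± 0.04 was below the control level of 1.11 ± 0.09, and tamoxifen brought it to 1.60 ± 0.03. A large fall was at Z00027744-1 (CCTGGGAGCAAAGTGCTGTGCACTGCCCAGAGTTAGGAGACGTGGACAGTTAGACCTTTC), from 0.11 ± 0.07 to -3.05 ± 0.19, a log2 change of -3.16 (SE 0.08, limma adjusted p = 8.25e-09). Probe Z00010943-1 (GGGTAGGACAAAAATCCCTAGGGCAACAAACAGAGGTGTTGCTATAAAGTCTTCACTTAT) fell from 0.54 ± 0.12 to -2.44 ± 0.27, and was well above background on 1 of the 3 induced arrays, so the size of its fall is uncertain. With Agilent's processed ratio the log2 change of Z00003224-1 was 2.50 against 2.23 for Z00015795-1. With offset 50, the 12 largest rises had log2 changes of 1.55 to 2.07 and the 12 largest falls -2.09 to -3.16.

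**Figure D1:**
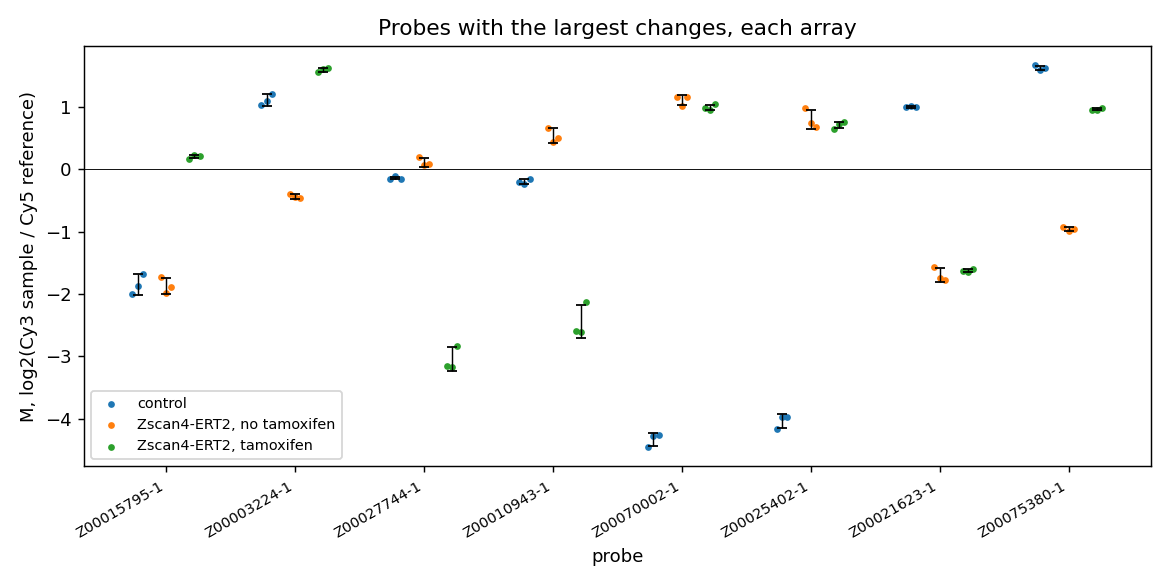
M, the log2 ratio of Cy3 sample to Cy5 reference, on each of the 9 arrays for the probes with the largest rises and falls in Tmx+ vs Tmx- and in Tmx- vs control; dots are arrays, black marks the mean and SD of 3 arrays. At Z00070002-1 the control arrays average -4.33 and those of the Zscan4-ERT2 clone 1.11 without and 0.99 with tamoxifen.

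Transcripts that ES cells hold at a high level relative to the reference fell strongly more often than they rose. Of the 1324 probes at least 2-fold above the reference in control cells (ES-high probes), 55 fell at least 2-fold with tamoxifen and 16 rose, which is 4.15% and 1.21% of the class. Of the 2820 probes at least 2-fold below the reference in control cells (reference-high probes), 32 fell and 30 rose at least 2-fold, and of the 20613 between these bounds 111 fell and 59 rose. The balance of the reference-high probes depended on the background correction, with 73 falls and 103 rises in Agilent's processed ratio and 38 and 57 with offset 10, while falls outnumbered rises among ES-high probes in both. The classes were set on the control arrays alone, which do not enter this comparison, and were chosen after the data were seen. Shifts of the class medians were small, -0.08 for ES-high and 0.06 for reference-high probes. Limma's fry on the 6 arrays gave an adjusted p of 0.0347 for each class. Camera gave adjusted p = 0.000357 and 0.004 with a preset correlation and adjusted p = 0.469 for both with an estimated correlation. The estimate was 0.237 for ES-high and 0.117 for reference-high probes, well above the preset 0.01, so the small p-values of the preset carry little weight. Within slide 2, which held 2 arrays of each group, the class medians were -0.03 and 0.04. The fit with slide as a block estimates this comparison within slide 2, so its equal medians are no second check.

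Probes of closely related sequence moved together. Among the tested probes, 1155 fell into 522 families with at least 85% identity over at least 40 bases. Probes this alike may read the same transcript, which was not tested. A shared direction within a family may therefore be a single measurement. In the 468 families of 2, the log2 changes of the partners correlated at r = 0.968 across pairs, which are not independent replicates, and in each of the 182 pairs with both partners called, the partners moved the same way. The largest family had 13 probes of low intensity, and all 13 fell with tamoxifen, by a log2 change with a median of -0.47, which was -0.87 with Agilent's processed ratio and -0.62 with offset 10. This direction held for all 13 under the other background corrections and scalings, with the Cy3 channel alone calling 8.

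Within slide 2, 5626 probes were higher and 4311 lower in induced cells, and 6168 and 4689 with slide as a block. When the Cy3 signal was used without the reference channel, 1183 probes were higher and 1384 lower, and of the 303 probes changed at least 2-fold, 299 were still called in the same direction.

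The second comparison, the uninduced Zscan4-ERT2 clone against the control clone, addresses how the cells differed before induction. Clone, transgene and days of culture differ together here. The strongest differences were transcripts far below the reference level in control cells and near or above it in the uninduced clone. Probe Z00070002-1 (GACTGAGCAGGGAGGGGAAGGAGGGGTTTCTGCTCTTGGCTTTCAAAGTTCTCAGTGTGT) had M of -4.33 ± 0.11 (SD, n = 3) in control and 1.11 ± 0.08 (SD, n = 3) in the uninduced clone, a log2 change of 5.45 (SE 0.06, limma adjusted p = 4.49e-11). Probe Z00025402-1 (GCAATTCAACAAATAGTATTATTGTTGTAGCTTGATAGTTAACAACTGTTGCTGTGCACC) was higher by a log2 change of 4.84 (SE 0.08, limma adjusted p = 5.71e-10), and by more than Z00070002-1 in Agilent's processed ratio, 6.83 against 6.53. With offset 10 the changes were 5.80 for Z00025402-1 and 6.07 for Z00070002-1. The size of both thus depended on the background correction, which the SE does not cover. A large reduction was at Z00021623-1 (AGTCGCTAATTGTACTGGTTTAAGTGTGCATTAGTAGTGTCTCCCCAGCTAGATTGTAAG), from 1.00 ± 0.01 in control to -1.69 ± 0.11, a log2 change of -2.70 (SE 0.05, limma adjusted p = 2.36e-09). Probe Z00075380-1 (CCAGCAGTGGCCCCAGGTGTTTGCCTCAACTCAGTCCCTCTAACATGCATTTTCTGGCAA) was lower by a log2 change of -2.58 (SE 0.04, limma adjusted p = 2.62e-10).

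In total 2577 probes were higher and 2737 lower in the uninduced clone than in control, 28 and 63 of them at least 2-fold. The 2-fold counts were 99 and 186 in Agilent's processed ratio and 96 and 158 in the deposited value table. Median centring in place of loess gave 2068 higher and 987 lower probes. The count of higher probes fell whichever control array was left out. It was 1648 without control replicate 1, 1525 without replicate 2 and 1613 without replicate 3. Without replicate 2 the count of lower probes was 1802. With any 1 array left out, the 2-fold counts were 24 to 30 higher and 60 to 63 lower. Within slide 1, which held the 3 control arrays and 1 uninduced array, 5003 probes were higher and 3806 lower, and with slide as a block 5679 and 4294. Both rest on 1 array of the uninduced clone, Tmx- replicate 1, and within slide 1 the spread came from the control arrays alone, so they do not show how uninduced arrays vary. The Cy3 channel alone called 169 higher and 389 lower.

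Of the 11 probes at least 4-fold higher in the uninduced clone than in control, 10 were not called changed by tamoxifen, and the log2 changes of these 10 with tamoxifen lay between -0.32 and -0.03. In control, 5 of the 11 were not well above background on any array, nor were 7 of the 28 probes at least 2-fold higher, so the size of these rises is uncertain. Of the 28, 18 were not called changed, 5 rose further and 5 fell. Of the 63 probes at least 2-fold lower in the uninduced clone, 49 rose with tamoxifen, 0 fell and 14 were not called changed. Their median log2 change was -1.24 between clones and 0.55 with tamoxifen. The shared uninduced arrays favour such a course, and it was checked in 2 ways chosen after the data were seen. Groups simulated with the clone differences but no effect of tamoxifen gave on average 1.05 rises, and at most 4, among 65.7 such probes. The simulated noise was independent between arrays. Whether arrays of a slide deviate together is not settled. The fit with slide as a random block estimated a correlation of 0.547 within slides. Residuals around the group means instead correlated at -0.0693 on average, over 7 pairs of arrays from different groups on the same slide. Independent noise does not cover deviations that the uninduced arrays have in common. With slide as a block, where different uninduced arrays enter each comparison, 51 of 92 such probes rose, 6 fell and 35 were not called changed; the clone difference then rests on 1 uninduced array, Tmx- replicate 1, which stood apart from its group. Among the 10 largest reductions, 8 rose with tamoxifen.

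A set of 16 probes was at least 2-fold lower in the uninduced clone than in control and at least 2-fold higher again with tamoxifen. Their median log2 change was -1.31 between clones and 1.26 with tamoxifen, and the difference left between induced cells and control was -0.67 to 0.49. Choosing probes for both changes favours such a return to near the control level. Lists of these sizes drawn independently would share 0.267 probes. The opposite course, at least 2-fold higher in the uninduced clone and at least 2-fold lower with tamoxifen, was taken by 2 probes, where independent lists would share 0.224. The numbers were 55 and 14 with Agilent's processed ratio and 45 and 17 in the deposited value table. Probes Z00003224-1 and Z00075380-1 belong to the set of 16.

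**Figure D2:**
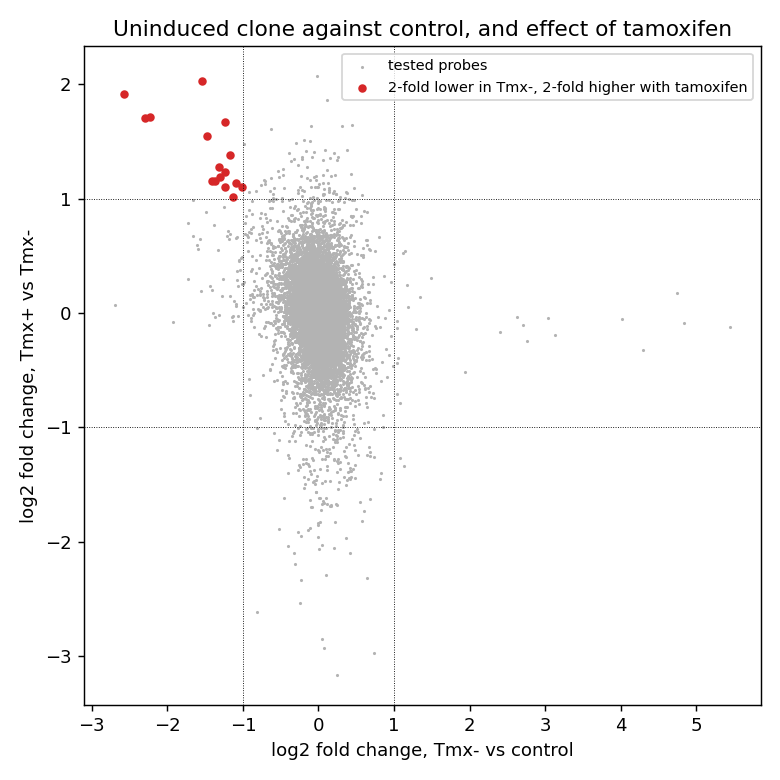
Log2 fold change of each of the 24757 tested probes in the uninduced clone against control (horizontal) and with tamoxifen against without (vertical); dotted lines mark 2-fold changes. The 16 probes in red lie at least 2-fold down on the horizontal and at least 2-fold up on the vertical axis.

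Across all probes called in Tmx+ vs Tmx-, 34.3% had the same sign in Tmx- vs control. Both comparisons share the uninduced arrays, so chance alone makes their signs oppose. In simulated unchanged groups sharing those arrays the share was 22.2%, and the correlation of the log2 changes across probes was -0.498 against -0.244 observed. The simulated share and correlation hold for groups without any change and are not the level for probes with real changes. They do not show whether the observed signs opposed more or less than by chance. The observed covariance was -0.0139 and the simulated one -0.00279, a difference of -0.0111. Probes lower in the uninduced clone and higher with tamoxifen numbered 1283, where independent lists would share 575, and those taking the opposite course 990, where independent lists would share 443. With slide as a block, the comparisons rest on different uninduced arrays, 1 for the clone difference and 2 for tamoxifen. The numbers were then 1469 where independent lists would share 1070, and 1456 where they would share 1076. The share was then 47.8%, the correlation -0.058 and the covariance -0.00434, and the 2-fold set again held 16 probes, 15 of them the same. Part of the excess of opposite changes may come from the shared arrays.

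The third comparison, the induced clone against control, combines clone and tamoxifen, and no slide held arrays of both groups. Here 5339 probes were higher and 4550 lower, 141 and 220 of them at least 2-fold. The 2-fold counts were 438 and 541 in Agilent's processed ratio and 401 and 448 in the deposited value table. Median centring in place of loess gave 5168 higher and 2515 lower probes. Of the 141 higher probes, 126 were also called higher in induced than in uninduced cells and 84 were already higher in the uninduced clone. Of the 220 lower probes, 199 were called lower with tamoxifen and 103 were already lower without it. These comparisons share arrays with the one that selected the probes, which favours the same direction. Among the largest excesses over control was again Z00070002-1, with a log2 change of 5.32 (SE 0.06, limma adjusted p = 5.55e-11). Another was at Z00064853-1 (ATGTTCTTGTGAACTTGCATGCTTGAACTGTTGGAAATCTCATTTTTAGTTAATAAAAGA) with 4.93 (SE 0.05), a probe well above background on 2 of the 3 control arrays, so the size of its excess is uncertain. A large reduction was at Z00004852-1 (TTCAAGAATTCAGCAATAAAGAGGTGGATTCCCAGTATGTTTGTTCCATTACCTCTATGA), a log2 change of -3.44 (SE 0.04, limma adjusted p = 5.98e-11), built from -0.82 between clones and -2.62 with tamoxifen. With slide as a block, 6667 of the 9889 calls kept their direction and their call, 268 probes were at least 2-fold higher than control, and the Cy3 channel alone called 1167 probes higher and 1770 lower.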

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

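The alternatives were planned before the data were examined, except slide position as a block, leaving out the position 4 arrays, leaving out sequence families, and the recomputing of 2-fold counts, of the set of 16 probes and of class medians under each setting. No named probe changed direction or lost its call under any alternative that gave it a value. Requiring 2-fold changes reduced the counts to 105 higher and 198 lower for Tmx+ vs Tmx-, 28 and 63 for Tmx- vs control, and 141 and 220 for Tmx+ vs control. The Cy3 channel alone called 1183 and 1384, 169 and 389, and 1167 and 1770 in the same order, with a median SE of 0.113 against 0.0552 for the ratio. Higher calls were then 30.3% of all calls in Tmx- vs control and 39.7% in Tmx+ vs control, against 48.5% and 54.0%. Median centring in place of loess gave 2658, 987 and 2515 lower probes, and 67.7% and 67.3% of the calls against control were then higher. The deposited value table, which tests other probes, gave 3088 and 2823, 1472 and 1523, and 3221 and 2941. Its 2-fold counts were 337 and 398, 96 and 158, and 401 and 448. Agilent's processed ratio gave 2-fold counts of 375 and 487, 99 and 186, and 438 and 541. Offset 10 gave 197 probes 2-fold higher in Tmx+ vs Tmx-, 100 lower in Tmx- vs control and 250 higher in Tmx+ vs control. Requiring signal in both channels on all 9 arrays left 15 probes 2-fold higher in Tmx- vs control. Slide as a fixed block gave 5679 higher and 4294 lower probes in Tmx- vs control and 268 probes 2-fold higher in Tmx+ vs control, slide as a random block 4382 higher in Tmx- vs control, and slide 1 alone 5003. The causes of these shifts were not tested.

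The share of tamoxifen-called probes with the same sign in Tmx- vs control, 34.3%, was 34.8% without background correction, 36.8% with median centring, 37.2% after scale normalization, 36.2% with Cy3 alone, 33.8% without the filter, 47.8% with slide as a fixed and 38.1% with slide as a random block, and 33.7% in the deposited table. Leaving out 1 array at a time gave 31.2% to 35.8%. The counts then ranged from 4209 to 6357 higher and 3429 to 4597 lower in Tmx+ vs Tmx-, 1525 to 2808 and 1802 to 3691 in Tmx- vs control, and 4169 to 6842 and 3632 to 5627 in Tmx+ vs control. Where 1 array was left out, the pair left was taken to vary like the other groups.

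Arrays with the same replicate number did not deviate together: the mean correlation of their residuals was -0.086, from -0.403 to 0.173, and the numbers do not pair the samples. With the replicate number as a block, 4668 and 3807 probes were called in Tmx+ vs Tmx-, 1980 and 2220 in Tmx- vs control, and 4776 and 4182 in Tmx+ vs control. Without Tmx- replicate 1 and Tmx+ replicate 2, the arrays at position 4, 5615 and 4036 probes were called in Tmx+ vs Tmx-. Not run for lack of gene names were all alternatives for the gene lists and Zscan4, and the mean of the probes of a gene; keeping all probes is what was done. Probes not well above background in any group, 17249 of 42006, allow no statement.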

Other observations

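Of the tests in this part, those of the shared arrays and of the clone difference in tamoxifen-changed probes, of the slide positions (with position as a block), of the strong falls within the classes and of the splits of the samples were chosen after the results were seen, and the patterns themselves were found in the same data.

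Of the 105 probes at least 2-fold higher with tamoxifen, 47 were lower in the uninduced clone than in control, 16 were higher and 42 were not called different. Of the 198 probes at least 2-fold lower with tamoxifen, 71 were higher in the uninduced clone, 35 were lower already and 92 were not called different. The shared uninduced arrays favour opposite signs. Simulated groups with the tamoxifen changes but no clone difference gave at most 6 lower and 3 higher among 114 probes on average of the first kind. They gave at most 4 higher and 3 lower among 201 of the second. Their noise was drawn independently for each array, so a deviation common to the uninduced arrays was not covered. With slide as a block, where the clone difference rests on 1 uninduced array, 50 of 135 were lower and 38 higher, and 77 of 179 were higher and 29 lower. The GC content of the probes had a Spearman correlation of 0.00225 with the log2 change with tamoxifen across probes and of -0.156 with the clone difference. Its median was 40% in probes at least 2-fold higher with tamoxifen and 43.3% in those at least 2-fold lower, against 45% in all tested probes.

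The 16 probes were at least 2-fold lower in the uninduced clone and at least 2-fold higher with tamoxifen. They raise the hypothesis that part of what distinguished the uninduced clone from control was undone with tamoxifen. Independent chance values of the shared uninduced arrays do not account for the set. In the 6 ways to take the clone difference and the tamoxifen change from different uninduced arrays, at least 14 such probes remained. These were counted on group means, and independent lists would share at most 0.494. A single deviating array does not account for the set either, as at least 14 remained whichever array was left out. Nor does the reference channel, as the Cy3 signal alone gave 12. A deviation common to all uninduced arrays would pass each of these checks. It is not excluded, as the labels do not say whether the replicates were separate cultures. What also stays open is which difference of the uninduced clone the probes follow, since clone, transgene and days of culture differ together from control, and which genes they measure. Whether their rise came from tamoxifen itself is open too, as no array held the control clone with tamoxifen. Low activity of the fusion protein without tamoxifen was not tested.

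The shift of the class medians, with ES-high probes lower and reference-high probes higher after tamoxifen, may come from a difference in the spread of ratios between arrays. The gap between the medians was 0.137, with an SD of 0.0714 between arrays, and fell to 0.0495 after scale normalization and to 0.0627 within slide 2. The Cy3 channel alone, which uses no reference, gave a gap of 0.152, so the reference channel does not account for it, and the smallest gap with 1 array left out was 0.0979, which does not exclude a single array given that SD. A true change of the ES-high transcripts cannot be told apart from a narrower spread for the medians. The excess of strong falls among ES-high probes stayed after scale normalization, with 53 probes at least 2-fold lower and 22 higher, and with slide as a block, with 51 and 24. Over all tested probes the counts were 193 and 108, and 179 and 135. Scale normalization moved the ES-high median only from -0.078 to -0.0387. A shift of that size could hardly remove 2-fold falls, so their persistence decides little.

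Arrays at the same position of different slides tended to deviate from their group means together, with a mean correlation of residuals of 0.207 over the 6 pairs of the same position, from 0.0207 to 0.451, and -0.0595 over the other pairs, and 4 of the 216 arrangements of the positions within the groups gave a difference as large (exact permutation, one-sided p = 0.0185). Position was 1 of 3 structures tried, beside replicate number and slide, and adjusted over these the p was 0.0556. The highest, 0.451, joined Tmx- replicate 1 and Tmx+ replicate 2, both at position 4, where mean Cy3 intensity was also the highest, 2122 and 2151. The pattern was seen before it was tested, so chance is not excluded, and position and brightness cannot be told apart because the brightest array of slides 1 and 2 lay at position 4. Slide position as a block gave 5058 higher and 4183 lower probes in Tmx+ vs Tmx-, and no biological explanation was tested.

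Splitting 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. Each other split mixes both groups, so a large difference between them widens the spread. Counts of 0 are then likely whatever the source of the difference, and they decide nothing about it. In Tmx+ vs Tmx- the real split called 9464 probes and the highest other split 0, and 1 split of 10, the real one, reached that number. In Tmx- vs control the numbers were 5314 and 0, and in Tmx+ vs control 9889 and 0, again with 1 split of 10.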
